A study of Mus musculus with 9 samples.

How the data were processed

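Polyadenylated RNA of the mouse melanoma cell line YUMM1.1 was sequenced in 9 strand-specific libraries. Per the labels' protocols, RNA was extracted with TRIzol and cleaned on RNeasy columns with an on-column DNase step. The labels put 3 libraries in each of 3 groups: control (non-targeting guide), resistant (a clone selected for 6 weeks with vemurafenib) and Sox10_KO (drug-naive cells with a CRISPR guide against Sox10). They call the 3 libraries of a group technical replicates. No 2 libraries held identical values, and each library was counted as 1 replicate.

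The deposited table held 19675 genes in 9 columns, all of which were used. Its values were of the unit called signal here: gene-level read counts that the authors had divided by a size factor per library, as inferred from the deposited values, which were not whole numbers. The median ratio of each library to the gene-wise geometric mean was 1.0008 in all 9 columns, as such a scaling gives. Per the submitters' processing notes, kallisto 0.45.0 and DESeq2 were used, and the builds mm9 and GRCh38 were named without a role. The annotation, the transcript-to-gene step and any filter on genes are not given in the sources used here. Whole reads could not be recovered from the values, since only 50.9% to 67.1% of low values per library lay within 0.1 of a whole number of reads. A count model was therefore not used. The test planned for counts was replaced by the one planned for normalized values.

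The value of 1 read per library was estimated from the spacing of the low values, and dividing each library's total by it gave the depths in the report. A floor of 3 reads was used for genes listed at 0, and where a list held such genes its median was also computed with them held at that bound. The bound replaced only the level of the group listed at 0, and the other group kept its own mean. The floor covers counting error only, and reads without molecular identifiers are not independent molecules.

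Genes with a value of at least 10 in at least 3 libraries were kept, which left 14583. Values were transformed as log2(value + 1) and fitted in R 4.3.3 with limma 3.58.1, with a mean-variance trend, over all 9 libraries with group as the only term, so that the groups shared an estimate of the spread. Resistant was compared with control, Sox10_KO with control, and resistant with Sox10_KO. P-values were two-sided and were adjusted over genes by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05, and counts are also given for a fold change of at least 2. Fold changes in the text were computed on the log2(value + 1) scale. The overlap of both comparisons with control was set beside that of independent lists and beside 100 simulated data sets in which no group differed. Tables were checked and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

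The groups, comparisons, gene lists, rule for named genes and most of the other settings tried were fixed before the data were examined. The 30 lists covered the SOX family, pigmentation and melanocyte differentiation, neural crest and glial genes, dedifferentiated AXL-high melanoma genes, receptor tyrosine kinases and ligands, ERK pathway output, YAP and TEAD targets, mesenchymal genes, extracellular matrix, TGF-beta response, interferon response, MHC class I antigen presentation, NF-kB and inflammatory cytokines, proliferation, p53 targets, ATF4 stress response, hypoxia and glycolysis, cholesterol biosynthesis, oxidative phosphorylation, drug efflux transporters, SOX9 cartilage targets, WNT response and immediate early genes. They also covered markers of endothelium, fibroblasts, macrophages and leukocytes, keratinocytes, and muscle and erythroid cells, and mitochondrially encoded and ribosomal protein genes. Each list was tested in limma with camera at a preset correlation of 0.01, adjusted over the 30 lists within a comparison, and again with the correlation estimated. The estimated version gave larger p-values even where the estimate lay under the preset value. Fibroblast markers in Sox10_KO against control had an estimate of 0.00039, and camera's unadjusted p went from 0.00077 to 0.013. Calls lost with it therefore need not reflect correlation among members. Members were counted as higher or lower by the adjustment over all genes and again adjusted over the list alone.

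The named genes were, in each comparison, 15 genes fixed by name and the 8 largest increases and 8 largest decreases among called genes with a mean of at least 10 CPM (values rescaled to library totals) in the higher group and no overlap between the libraries of the groups. Predicted and unnamed gene models were left out. The rule also gave the 3 members of each list with the largest change under the same conditions, from which the text leaves out some genes of lists that it only counts. With 3 libraries against 3, chance gives non-overlap in 10% of genes.

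The procedure was tested on simulated data with 200 genes changed by known folds. All libraries were drawn from the control means and spread, so a group with a wider spread may give lower shares. The median SD of log2 values, over 10582 genes of higher level, was 0.097 in control, 0.075 in resistant and 0.128 in Sox10_KO libraries. Among changed genes at a level of 100 or more, 79.3% of 1.5-fold, 93.2% of 2-fold and 100% of 4-fold changes were found for resistant against control (13642 genes; 158 calls, of which 10 were false). The shares were 75.8%, 96.6% and 100% for Sox10_KO against control (13638 genes; 161 calls, 9 false) and 77.3%, 95.3% and 100% for resistant against Sox10_KO (13614 genes; 168 calls, 9 false). At a level of 10 to 100, 50%, 50% and 60% of 4-fold changes were found in these comparisons, so smaller changes of low genes were mostly not detectable.

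Alternatives were pseudocounts of 0.1 and 5, no low-value filter, a stricter filter (a mean of at least 10 CPM), scaling to equal library totals, a fit of only the groups compared, the replicate number as a block, a test against a 1.5-fold change, each library left out in turn, and for lists an estimated correlation and limma's fry test. Quantile normalization and library weights were added after the data were seen. For 1 library that stood apart, 9 lists of cell type markers were written after it was seen to differ and before they were tested: neuron, neural progenitor, astrocyte, oligodendrocyte, hepatocyte, cardiomyocyte, pluripotent stem cell, lymphocyte and epithelium. Chromosome, GC content and gene type came from the GENCODE M21 annotation of GRCm38, matched by symbol for 96.2% of the genes used. Since the build behind the values is not settled, no coordinates are given.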

Results

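Polyadenylated RNA was sequenced from YUMM1.1, a mouse melanoma cell line that the labels describe as Braf-mutant, Pten-null and Cdkn2-null. Control cells carried a guide with no target. Sox10_KO cells were drug-naive cells that received a CRISPR guide against the N-terminal part of Sox10, a transcription factor of the neural crest and of melanocytes. Resistant cells were selected for 6 weeks with vemurafenib, an inhibitor of mutant BRAF, and all 3 resistant libraries came from the same clone according to their labels. Differences from control can therefore be those of this clone. According to the labels the resistant libraries carried no guide, unlike control and Sox10_KO cells, so the presence of a guide differed along with drug selection. Whether drug was present at harvest is not given in the sources used here. Each group had 3 libraries, which the labels call technical replicates. The p-values therefore measure only the spread between libraries, which may be technical, and not the spread between independently derived cultures.

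The values were read counts divided by size factors. They summed to between 30390873 and 33043229 per library, and the estimated depth ran from 25249193 reads in Sox10_KO replicate 2 to 37682638 in control replicate 1. A floor of 3 reads corresponded to values of 2.63 to 3.61, which covers counting error only. Of 19675 genes, 14583 passed the low-value filter and were tested with limma. Levels are means ± SD of normalized counts over 3 libraries. Fold changes are on the log2(value + 1) scale with their SE, which understates the change of genes with low values.

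Sox10_KO replicate 2 stood apart from the other 8 libraries. It listed 888 genes at 0, against 1649 to 2241 in the others, and its lowest correlation with a library of its own group was 0.938, against 0.984 between replicates 1 and 3. In it, 67 genes stood at 1000 or more that stood at 50 or less in every other library. Transcripts of neurons were among those it gained. Stmn2 reached 4419.2, Dcx 1751.8, Elavl4 1731.3 and Snap25 1028.5 in this library, and none of these 4 exceeded 24 elsewhere; they and Sox11 were singled out here after their values were seen. All 9 libraries were kept in the fit. Values without this library are given beside the lists and genes named below where it changed a call or moved a count by over 1.5 times.

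**Figure D1:**
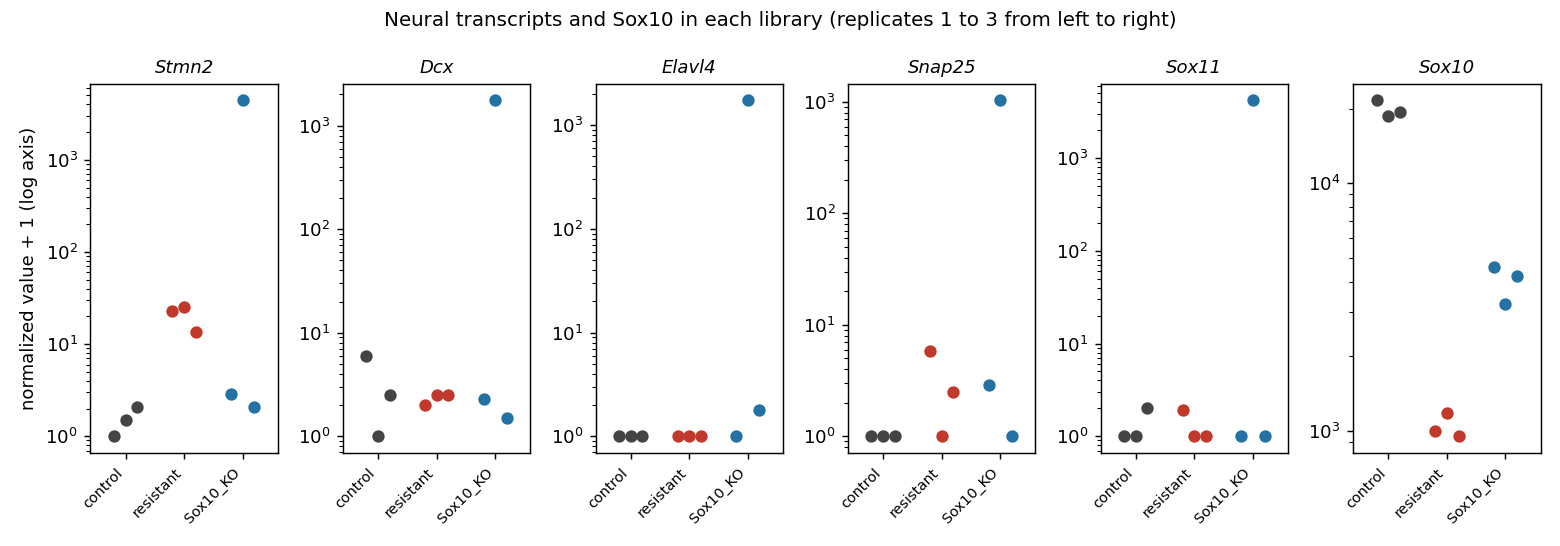
Normalized counts plus 1 (log axis) of Stmn2, Dcx, Elavl4, Snap25, Sox11 and Sox10 in each library, with replicates 1 to 3 of a group from left to right. Sox10_KO replicate 2 stands alone for the neuronal transcripts, with Stmn2 at 4419.2, while its Sox10 value of 3251 lies near those of the other Sox10_KO libraries.

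The targeted gene was examined first. Sox10 stood at 21581, 18733 and 19411 in control replicates 1 to 3, at 996, 1182 and 947 in resistant replicates 1 to 3, and at 4566, 3251 and 4215 in Sox10_KO replicates 1 to 3. Its log2 fold change from control was -2.32 ± 0.13 in Sox10_KO cells (5-fold lower; adjusted p = 2.24e-07, limma) and -4.26 ± 0.13 in resistant cells (19.1-fold lower; adjusted p = 2.37e-09). The resistant libraries, which carried no guide according to the labels, thus held 3.83-fold less Sox10 transcript than the Sox10_KO libraries (adjusted p = 2.44e-06). The protein was not measured here.

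The series title names Sox9, Sox6 and Sox7, so the SOX genes were followed across the 3 groups. Sox9, a related factor of neural crest and cartilage, rose from 305.9 ± 37.3 in control to 2224 ± 23.8 in resistant and 3405 ± 182 in Sox10_KO cells. Its log2 fold changes were 2.87 ± 0.09 and 3.48 ± 0.09 (adjusted p = 2.67e-09 and 1.21e-09, limma), and it was 1.53-fold lower in resistant than in Sox10_KO cells (adjusted p = 0.000309). Sox6 fell from 1730 ± 271 to 136.3 ± 35.6 in resistant cells (12.8-fold) and to 469.1 ± 196 in Sox10_KO cells (3.87-fold). Sox7 moved the opposite way, from 34.4 ± 4.51 to 310.9 ± 6.86 (8.86-fold) and 220.6 ± 26.1 (6.26-fold). Sox7 was 1.41-fold higher in resistant than in Sox10_KO cells (adjusted p = 0.0304), a call that ended without Sox10_KO replicate 1 or 2 (adjusted p = 0.0623 and 0.079), without resistant replicate 1, 2 or 3 (0.0752, 0.0832 and 0.091), with the replicate block (0.053) and with quantile normalization (0.169). Sox5 differed by less than the spread between libraries, at 360.9 ± 80.9, 365.4 ± 52.4 and 349.4 ± 35. Sox4 stood at 8421 ± 254 in control and 5162 ± 101 in resistant cells, and at 3106, 9860 and 3200 in Sox10_KO replicates 1 to 3. With all libraries neither Sox4 difference from control passed (adjusted p = 0.117 and 0.0613); without Sox10_KO replicate 2 both did, at log2 fold changes of -0.71 and -1.42 (adjusted p = 1.16e-07 and 2.13e-09). Both also passed with library weights (adjusted p = 0.00344 and 5.79e-05), the resistant difference with only the groups compared (7.61e-07) and the Sox10_KO difference with the stricter filter (0.0452). Between the derived lines Sox4 was not called (adjusted p = 0.744), but it was without Sox10_KO replicate 2, at a log2 fold change of 0.71 (adjusted p = 1.1e-06), and with library weights, at 0.61 (adjusted p = 0.00635). Of 10 tested members of the SOX family list, 3 rose and 2 fell in each comparison with control, also when adjusted over the list alone. Without Sox10_KO replicate 2 these counts were 3 and 5 in each. The list as a whole was not called (camera adjusted p = 0.81 in resistant and 0.91 in Sox10_KO cells).

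**Figure D2:**
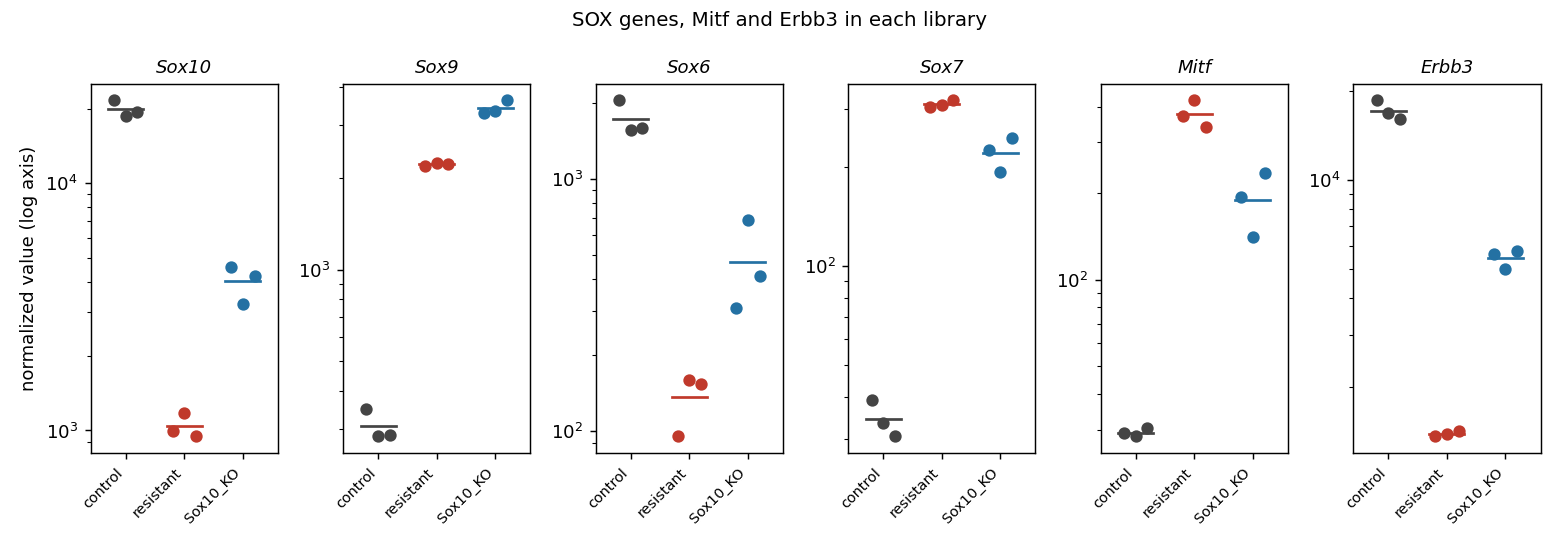
Normalized counts (log axis) of Sox10, Sox9, Sox6, Sox7, Mitf and Erbb3 in control, resistant and Sox10_KO libraries; points are libraries and bars are group means. Sox10, Sox6 and Erbb3 are lower and Sox9, Sox7 and Mitf higher in both derived groups than in control, with Sox9 at 305.9 in control, 2224 in resistant and 3405 in Sox10_KO cells.

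The comparison of resistant with control cells asks which transcripts set the vemurafenib-selected line, which carried no guide, apart from drug-naive cells with a non-targeting guide. All 27 tested interferon response genes and all 9 fibroblast markers rose. Both list calls held with an estimated correlation (camera adjusted p = 0.02 and 0.041), but not when Sox10_KO replicate 2 was also left out (0.067 for both). That library is in neither group compared, and without it the list medians stayed at 5.11 and 5.36. At the preset correlation camera then gave adjusted p-values of 3.2e-15 and 1.7e-05. Most neural crest, glial and cholesterol synthesis genes fell, list calls that were lost with an estimated correlation (adjusted p = 0.31 for both). Receptor tyrosine kinases and their ligands split evenly, with 10 of 27 higher and 10 lower. At an adjusted p threshold of 0.05, 4171 of 14583 genes were higher and 3912 lower, of which 1957 and 1002 changed at least 2-fold. Quantile normalization, added after the data were seen, gave 1546 and 1602 in place of these last 2 counts. The largest increases included Ccn5, a matricellular protein (1.14 ± 1.25 in control, 10410 ± 338 in resistant cells), Scara3 (0.987 ± 1.02 to 3732 ± 137), Plxnc1, a semaphorin receptor (1.05 ± 0.914 to 3662 ± 321), Pdgfrb, the PDGF receptor beta (0.629 ± 0.55 to 2625 ± 87.7), and Oasl2, an interferon-induced gene (2.68 ± 2.61 to 4329 ± 250). The complement protease gene C1s1, the matricellular gene Ccn4 and Nxf3 were listed at 0 in all 3 control libraries and reached 3611 ± 325, 2712 ± 92.5 and 2547 ± 55.9. No fold is given for these 8 genes, whose control levels were near or under the floor. Among the largest decreases, the kallikrein genes Klk9 and Klk10 went from 6831 ± 511 to 12.6 ± 2.98 and from 7038 ± 615 to 93.3 ± 15.6. B4galnt3 went from 1698 ± 240 to 21.9 ± 7.28, Ajap1 from 1659 ± 302 to 5.51 ± 1.33, Malrd1 from 1125 ± 41.7 to 14.6 ± 4.39, Hsd3b6 from 5639 ± 241 to 98.2 ± 28.2, Rassf4 from 6198 ± 451 to 108.9 ± 8.83 and the neural factor Pou3f1 from 357.1 ± 69.1 to 4.8 ± 2.52. The adjusted p of these 16 genes was at most 0.00018 (limma). In each of them all 3 libraries of one group lay above all 3 of the other, as the naming rule required.

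Interferon response genes moved together in resistant cells. All 27 tested members were higher, over all genes and adjusted over the list alone, with a median log2 fold change of 5.11, or 4.76 with Oas1a, Oas2 and Rsad2, which were listed at 0 in control, held at their bound. Camera gave an adjusted p of 9.5e-16. With an estimated correlation the adjusted p was 0.02, or 0.067 without Sox10_KO replicate 2, which is in neither group compared. Ifit1 rose from 11.7 ± 4.36 to 7842 ± 644 and Rtp4 from 1.99 ± 1.78 to 2773 ± 185. Of 14 genes of MHC class I antigen presentation, 11 rose and 1 fell on both adjustments (camera adjusted p = 0.00046; adjusted p = 0.12 with an estimated correlation). Among them were the peptide transporter Tap2 (31.5 ± 13.3 to 609.8 ± 92.3), H2-T23 (5.26-fold) and H2-K1 (3.04-fold), while B2m, the light chain, fell from 30550 ± 1160 to 22760 ± 1560. NF-kB and cytokine genes rose in 11 of 17 and fell in 1, on both adjustments (camera adjusted p = 0.0014; adjusted p = 0.14 with an estimated correlation). In that list the cyclooxygenase Ptgs2 went from 27.7 ± 8.58 to 2951 ± 209, Vcam1 rose 6.91-fold and the chemokine Ccl7 6.02-fold. Near-identical copies exist among the Ifit, Oas, H2 and Klk genes, and reads could be split between them, so single values in these families are uncertain.

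Matrix and mesenchymal lists held genes that moved in both directions. Of 34 extracellular matrix genes, 19 rose and 11 fell, or 21 and 11 adjusted over the list alone (camera adjusted p = 0.032; adjusted p = 0.43 with an estimated correlation). Scaling to equal library totals also ended this call (adjusted p = 0.077). Col6a3 rose from 47 ± 29.4 to 19570 ± 1370, Fbn1, the gene of fibrillin-1, went from 1.1 ± 0.259 to 1078 ± 21.7, and Lum, listed at 0 in control, reached 498.2 ± 73.2. All 9 tested fibroblast markers were higher on both adjustments, with a median log2 fold change of 5.36, or 5.13 with Dpt and Lum at their bound (camera adjusted p = 2.4e-05). With an estimated correlation this had an adjusted p of 0.041, or 0.067 without Sox10_KO replicate 2, which is in neither group compared. Collagen Col1a1 rose from 181.8 ± 124 to 69920 ± 2980 and podoplanin, Pdpn, from 0.284 ± 0.492 to 903.4 ± 34. YAP and TEAD targets rose in 16 of 23 and fell in 3, or 17 and 4 adjusted over the list alone (camera adjusted p = 0.0018; adjusted p = 0.14 with an estimated correlation), with Asap1 3.97-fold and Crim1 3.75-fold higher. The 16 mesenchymal genes split into 7 higher and 6 lower, or 8 and 6 adjusted over the list alone (camera adjusted p = 0.47). Fibronectin, Fn1, rose 7.67-fold and Twist2 13.2-fold in it, while Mmp2 fell from 2082 ± 103 to 194.3 ± 28.3.

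Melanoma state and receptor genes changed in both directions in resistant cells. Of 20 genes of the dedifferentiated AXL-high melanoma list, 11 rose and 3 fell, or 11 and 4 adjusted over the list alone (camera adjusted p = 0.025; adjusted p = 0.48 with an estimated correlation). Wnt5a rose 6.41-fold and thrombospondin 1, Thbs1, 13.3-fold. Axl itself was lower, at 30160 ± 284 against 37070 ± 3130 (adjusted p = 0.0118, but 0.332 with quantile normalization), and so was the nerve growth factor receptor Ngfr, at 18240 ± 487 against 60250 ± 3760. Receptor tyrosine kinases and their ligands rose in 10 of 27 and fell in 10, on both adjustments (camera adjusted p = 0.8). The collagen receptor Ddr2 rose 20.8-fold, while Erbb3, a receptor of neuregulins, fell from 17190 ± 1290 to 1392 ± 27.2. Egfr stood at 23.8 ± 34.5 in control and 102.8 ± 14.5 in resistant cells (log2 fold change 3.34 ± 1.26; adjusted p = 0.0457), and leaving out any of 6 single libraries ended that call. The change ran from 2.21 without control replicate 2 to 4.67 without control replicate 1. Mitf, the melanocyte master regulator, rose 12.4-fold from a low 29.3 ± 0.96, and the lysosomal glycoprotein Gpnmb rose 7.58-fold. The 13 pigmentation genes as a list were not called (6 higher and 2 lower, 6 and 3 adjusted over the list alone; camera adjusted p = 0.38). Neural crest and glial genes fell in 14 of 19 and rose in 4, on both adjustments (camera adjusted p = 4.8e-05; adjusted p = 0.31 with an estimated correlation). Cdh19 fell 18.8-fold and the connexin Gjc3 14.9-fold, whereas the water channel Aqp1 rose from 78.5 ± 20.1 to 18270 ± 491.

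Growth-related lists followed in resistant cells. Cholesterol biosynthesis genes fell in 17 of 20 and rose in 1, on both adjustments (camera adjusted p = 2.1e-07; adjusted p = 0.31 with an estimated correlation); Nsdhl fell 2.84-fold and Fdps 2.52-fold, and the member that rose was Pcsk9, a regulator of the LDL receptor. Of 17 p53 targets, 13 fell and 3 rose, on both adjustments (camera adjusted p = 0.00072; adjusted p = 0.26 with an estimated correlation). Ccng1 was 2.91-fold and Aen 2.35-fold lower. Proliferation genes fell in 14 of 26 and rose in 2, on both adjustments (camera adjusted p = 0.011; adjusted p = 0.54 with an estimated correlation), with cyclin E1, Ccne1, 3.25-fold and Pcna 2.01-fold lower. The ERK output list moved both ways (6 higher and 7 lower of 19, or 7 and 8 adjusted over the list alone; camera adjusted p = 0.47). In it the feedback phosphatase Dusp6 stood at 9075 ± 455 against 7700 ± 166 (1.18-fold; adjusted p = 0.0087), Spry1 rose 6.35-fold and cyclin D1, Ccnd1, fell 2.93-fold. The 18 ATF4 stress genes were likewise not called as a list (10 higher and 6 lower on both adjustments; camera adjusted p = 0.38). Nupr1 rose 13.2-fold and Trib3 3.1-fold among them. Pten transcripts, in a line labelled Pten-null, were present at 3185 ± 17.3 in control and rose to 6684 ± 580. Braf and Cdkn2a did not differ (adjusted p = 0.417 and 0.976), with Cdkn2a at 387.8 ± 39.7 and 386.6 ± 42.2.

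The comparison of Sox10_KO with control cells asks what differed in cells with disrupted Sox10. The labels do not say whether these cells were a clone or a pool, so differences other than that in Sox10 can contribute. Most neural crest, p53 target and cholesterol synthesis genes fell and most proliferation genes rose, list calls that were lost with an estimated correlation (adjusted p = 0.45, 0.29, 0.45 and 0.45). Single genes that were almost undetected in control appeared at high levels. In total 4000 genes were higher and 3915 lower, of which 1571 and 1053 changed at least 2-fold (1224 and 1313 with quantile normalization). Leaving out Sox10_KO replicate 2 gave 1572 and 1197, and 2430 genes were shared between the 2 analyses. The largest increases were Serpinb9g, listed at 0 in control and at 2291 ± 138 in Sox10_KO cells, Ccn4 (0 to 860.8 ± 113), Fam167a (0.31 ± 0.536 to 1951 ± 291), Clmp (1.29 ± 2.24 to 1530 ± 49.4), Plxdc1 (1.49 ± 1.39 to 1429 ± 155) and Pdpn (0.284 ± 0.492 to 859.5 ± 22.8). With mean control levels above the floor, the aldehyde dehydrogenase Aldh3a1 rose from 6.92 ± 5.67 to 5249 ± 631 and the cyclooxygenase Ptgs1 from 10.4 ± 6.36 to 8432 ± 667. The log2 fold change of Aldh3a1 went from 9.74 to 8.95 without control replicate 3, where its value was low. Rasgef1c (468.6 ± 58.9 to 9.28 ± 7.26), Malrd1 (1125 ± 41.7 to 28.2 ± 16.1), Svip (437.8 ± 22.3 to 15.9 ± 23.7) and the glutamate receptor gene Gria3 (563.9 ± 11 to 78.9 ± 131) were among the largest decreases. The Gria3 mean rested on replicate 2, at 229.6 against 6 and 0.9, and its log2 fold change went from -5.28 to -7.28 without it; for Svip the change went from -5.83 to -7.08 and for Malrd1 from -5.49 to -4.87. The other 4 were the Y-linked genes Kdm5d (2545 ± 65.2 to 47 ± 19.6), Uty (1580 ± 97.1 to 26.4 ± 16.3), Eif2s3y and Ddx3y. Reads of these 4 could be shared with related X-linked genes, so their levels are uncertain, and no values are given for Eif2s3y and Ddx3y. Why Y-linked genes fell was not tested. Kdm5d and Uty were also lower in resistant cells, at 782.9 ± 52.8 and 551.6 ± 76.5.

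Proliferation genes rose in 22 of 26 and fell in 2 in Sox10_KO cells, or 24 and 2 adjusted over the list alone (camera adjusted p = 1.7e-06; adjusted p = 0.45 with an estimated correlation). Thymidylate synthase, Tyms, rose 2.34-fold, the replication licensing gene Mcm3 2.15-fold and survivin, Birc5, 2.11-fold. Of 17 p53 targets, 15 fell and 2 rose, on both adjustments (camera adjusted p = 6.4e-06; adjusted p = 0.29 with an estimated correlation), with Trp53inp1 4.82-fold and Plk2 3-fold lower. Cholesterol biosynthesis genes fell in 16 of 20 and rose in 1, on both adjustments (camera adjusted p = 2.4e-06; adjusted p = 0.45 with an estimated correlation), and lanosterol synthase, Lss, fell from 5463 ± 180 to 1487 ± 113. Neural crest and glial genes fell in 13 of 19 and rose in 3, on both adjustments (camera adjusted p = 0.00019; adjusted p = 0.45 with an estimated correlation). Gjc3 fell 10.5-fold, Cdh19 8.42-fold and Erbb3 3.15-fold, whereas Aqp1 rose 67.5-fold. ERK output genes fell in 11 of 19 and rose in 3, or 12 and 4 adjusted over the list alone (camera adjusted p = 0.011; adjusted p = 0.73 with an estimated correlation). Egr1 was 5.78-fold, Spry2 3.31-fold and Dusp6 1.35-fold lower. ATF4 stress genes fell in 11 of 18 and rose in 3, or 12 and 3 adjusted over the list alone (camera adjusted p = 0.011; adjusted p = 0.45 with an estimated correlation). Atf5 fell 4.5-fold and Atf3 2.63-fold. The cystine transporter Slc7a11 in that list stood at 942.9, 12062 and 1095 in Sox10_KO replicates 1 to 3, and its log2 fold change went from 2.59 to 1.4 without replicate 2.

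Matrix and immune lists gave a different picture in Sox10_KO cells. The 34 extracellular matrix genes split evenly, with 15 higher and 15 lower, or 16 and 15 adjusted over the list alone (camera adjusted p = 0.91). Their median log2 fold change was 0.07, their mean 0.73, and camera's direction was down. The median became -0.3 with Lum held at its bound in control. Lum also lay at or under the floor in Sox10_KO cells, where its own level was kept, so this value does not bound the median. Col6a3 rose from 47 ± 29.4 to 4282 ± 98.6. Col1a1 and Col1a2 were higher too, but most so in replicate 2, and their log2 fold changes went from 3.88 to 3.17 and from 6.16 to 5.36 without it. Fibroblast markers rose in 7 of 9, on both adjustments (camera adjusted p = 0.0046; adjusted p = 0.29 with an estimated correlation). Interferon response genes were not called as a list (13 higher and 8 lower of 27 on both adjustments; camera adjusted p = 0.77). Within it Gbp2 fell 2.84-fold and Ifit3 2.17-fold. MHC class I genes showed 2 higher and 3 lower of 14, on both adjustments (camera adjusted p = 0.35), with H2-K1 2.89-fold lower, and NF-kB and cytokine genes 9 higher and 3 lower of 17 (camera adjusted p = 0.15), again on both adjustments. Ptgs2 rose from 27.7 ± 8.58 to 2359 ± 117. The AXL-high list (9 higher and 3 lower of 20, camera adjusted p = 0.17), the receptor tyrosine kinase list (10 and 9 of 27, 0.76), the YAP and TEAD list (10 and 8 of 23, 0.76), the mesenchymal list (6 and 6 of 16, 0.97) and the pigmentation list (7 and 1 of 13, 0.14) were not called; adjusted over the list alone their counts were the same except 11 and 8 for YAP and TEAD targets and 8 and 1 for pigmentation. Without Sox10_KO replicate 2 the pigmentation counts were 7 and 2. The fibroblast growth factor receptor Fgfr1 rose 5.79-fold, Mitf 6.16-fold and Gpnmb 5.3-fold, while Axl was 1.37-fold lower (adjusted p = 0.00104). Egfr stood at 24.7 ± 36 and was not called (adjusted p = 0.918), nor were Braf (0.301) and Cdkn2a (0.167). Without Sox10_KO replicate 2 the log2 fold changes of Egfr and Braf turned, from 0.18 to -1.09 and from 0.33 to -0.03. Pten rose 1.44-fold to 4596 ± 233.

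**Figure D3:**
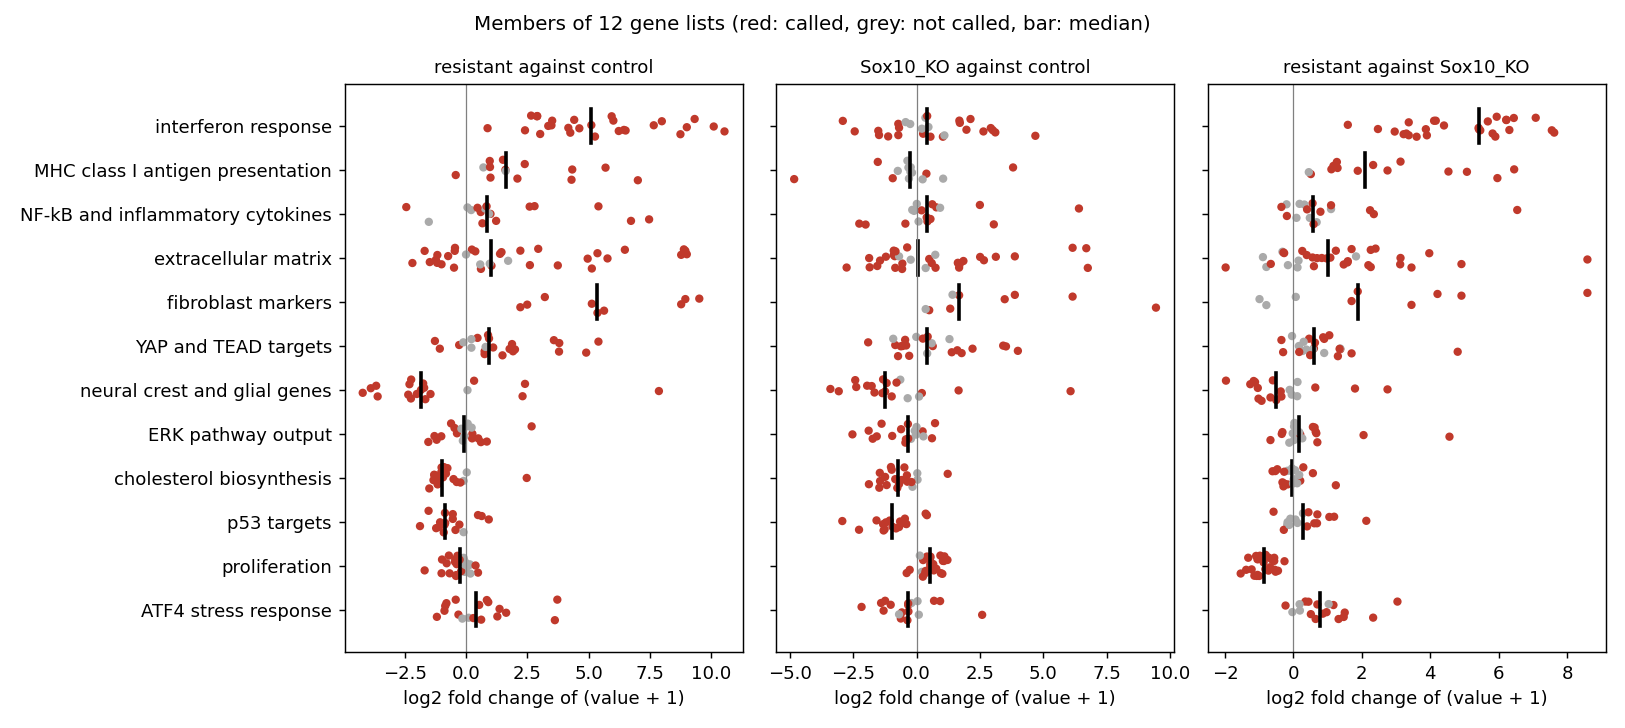
Log2 fold change of (value + 1) for the tested members of 12 gene lists in the 3 comparisons; red points are genes called at the adjusted p threshold of 0.05, grey points are not, and black bars are list medians. Interferon response genes lie high in resistant against control cells (median 5.11) and not in Sox10_KO against control cells (median 0.42), and proliferation genes lie above 0 in Sox10_KO cells (median 0.55).

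The 2 derived lines were then compared directly, which tests the difference between their departures from control. All 27 interferon response genes and 13 of 14 antigen presentation genes were higher in resistant than in Sox10_KO cells, matrix genes were higher in 23 and lower in 4 of 34, and all 26 proliferation genes were lower. With an estimated correlation the matrix and proliferation calls were lost (adjusted p = 0.085 and 0.095). Of all genes, 3335 were higher and 3085 lower in resistant cells, 1110 and 530 of them at least 2-fold (1014 and 845 with quantile normalization); without Sox10_KO replicate 2 these last 2 counts were 1366 and 536, and 1491 genes were shared. The largest increases were Lum (498.2 ± 73.2 in resistant cells) and Wnt10a (405.5 ± 5.53), both at or under the floor in Sox10_KO cells, then C1ra (8.52 ± 3.24 in Sox10_KO, 1987 ± 148 in resistant cells), Ifit1 (40.1 ± 12.4, 7842 ± 644), Ddx60 (4.87 ± 3.59, 1001 ± 182), Oasl2 (22.8 ± 7.11, 4329 ± 250), Frem1 (5.72 ± 9.92, 475.2 ± 61.4) and C1s1 (22.7 ± 8.36, 3611 ± 325). The largest decrease was that of Igfbp5, an insulin-like growth factor binding protein, at 9208 ± 254 in Sox10_KO and 106.2 ± 17.6 in resistant cells (86.7-fold; adjusted p = 1.45e-09, limma); control cells held 2640 ± 178. The retinoic acid binding protein Crabp1 was 34.1-fold, Klk9 32-fold, Mdga2 10.6-fold and Klhl1 10.4-fold lower. Zfp423, Nrxn2 and Rnf165 also met the naming rule, but replicate 2 carried them, at 1457.9, 3367.6 and 1801.9 against at most 41.3 in the other Sox10_KO libraries. Without it their log2 fold changes went from -4.77 to -2.88, from -4.41 to -2.07 and from -3.59 to -1.67, and that of Frem1 from 7.49 to 8.89. The Nrxn2 and Rnf165 calls were also lost in several other settings.

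All 27 interferon response genes were higher in resistant than in Sox10_KO cells, also adjusted over the list alone (median log2 fold change 5.41; camera adjusted p = 5.6e-22; adjusted p = 0.0082 with an estimated correlation). MHC class I genes were higher in 13 of 14 (camera adjusted p = 6.7e-08), with an adjusted p of 0.031 with an estimated correlation, or 0.13 without Sox10_KO replicate 2. All 26 proliferation genes were lower (camera adjusted p = 4.9e-17; adjusted p = 0.095 with an estimated correlation), with Ccne2 2.92-fold and Mcm5 2.61-fold lower. Matrix genes were higher in 23 of 34 and lower in 4, or 24 and 4 adjusted over the list alone (camera adjusted p = 1.1e-06; adjusted p = 0.085 with an estimated correlation), and fibroblast markers in 6 of 9 (camera adjusted p = 0.0082; adjusted p = 0.095 with an estimated correlation). ATF4 stress genes were higher in 13 of 18 and lower in 1, or 14 and 1 adjusted over the list alone (camera adjusted p = 1.1e-06; adjusted p = 0.085 with an estimated correlation), with Nupr1 8.2-fold and Trib3 5.01-fold higher. YAP and TEAD targets were higher in 13 of 23 and lower in 2 (camera adjusted p = 0.0011; adjusted p = 0.095 with an estimated correlation). NF-kB genes were higher in 8 of 17 and lower in 2, or 9 and 2 adjusted over the list alone (camera adjusted p = 0.017; adjusted p = 0.17 with an estimated correlation). Neural crest and glial genes were lower in 12 of 19 and higher in 3 (camera adjusted p = 0.0082; adjusted p = 0.46 with an estimated correlation). Where no second count is given, the counts adjusted over the list alone were identical. Not called were the SOX (1 higher and 4 lower of 10, camera adjusted p = 0.12), pigmentation (3 and 5 of 13, 0.53), AXL-high (7 and 1 of 20, 0.064), receptor tyrosine kinase (5 and 7 of 27, 0.92), ERK output (8 and 3 of 19, or 9 and 3 adjusted over the list alone, 0.053), mesenchymal (7 and 2 of 16, or 8 and 2 adjusted over the list alone, 0.053), p53 target (8 and 2 of 17, or 9 and 2 adjusted over the list alone, 0.074) and cholesterol (4 and 8 of 20, 0.25) lists. Without Sox10_KO replicate 2 the mesenchymal list was called (9 higher and 2 lower; camera adjusted p = 0.019; adjusted p = 0.17 with an estimated correlation). The counts also went to 2 and 3 for the SOX, 8 and 2 for the AXL-high and 8 and 5 for the p53 target list, and these lists stayed uncalled (camera adjusted p = 0.67, 0.11 and 0.19). The ERK output list was called with equal library totals (camera adjusted p = 0.048) and without resistant replicate 3 (0.041) or Sox10_KO replicate 1 (0.026) or 3 (0.019), against an adjusted p of 0.65 with an estimated correlation in all libraries. The mesenchymal list was also called without resistant replicate 3 (0.048) or Sox10_KO replicate 1 (0.05), and without Sox10_KO replicate 3 the p53 target (0.043) and AXL-high (0.05) lists were. With an estimated correlation in all libraries the adjusted p of these 3 lists was 0.17, 0.49 and 0.49. Spry1, a feedback inhibitor of receptor signalling, stood at 141.4 ± 10.4 in control, 902.1 ± 29.7 in resistant and 38.2 ± 9.87 in Sox10_KO cells. Dusp6 was 1.59-fold higher in resistant than in Sox10_KO cells (adjusted p = 2.18e-05). Mitf was 2.01-fold higher and Erbb3 3.91-fold and Ngfr 1.91-fold lower, and Pten was 1.45-fold higher. Axl, Egfr, Braf and Cdkn2a were not called (adjusted p = 0.154, 0.0676, 0.842 and 0.196); without Sox10_KO replicate 2 Egfr was, at a log2 fold change of 4.43 (adjusted p = 0.00482). Egfr was also called without control replicate 1 (0.0317) or 2 (0.0455), with a pseudocount of 5 (0.0493), with only the groups compared (0.039), with quantile normalization (0.0446) and with library weights (0.00126), and not in the other settings tried. Braf turned from -0.07 to 0.29 without Sox10_KO replicate 2 and stayed uncalled (adjusted p = 0.0653).

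Both derived lines shared much of their departure from control. Of the genes changed at least 2-fold, 1165 were higher in both and 592 lower in both, where independent lists of these sizes would share 211 and 72. Sox9, Aqp1, Ptgs2, Pdpn and Ccn4 were higher in both, and Sox10, Sox6, Erbb3, Cdh19 and Malrd1 lower in both. Only 34 genes moved in opposite directions, or 55 without Sox10_KO replicate 2, and Igfbp5 was among them. Over the 14583 genes, the log2 fold changes correlated at Pearson r = 0.76 across genes, which are not independent replicates, and 74.6% had the same sign. Both comparisons used the same 3 control libraries. Simulated libraries of all 3 groups, drawn around the control means, gave r = 0.5 and 66.7% of the same sign, and almost no shared calls. Only the spread between libraries was drawn, so a peculiarity of the control cells as a whole could not appear in them. The covariance was 1.55 against a simulated 0.069, a difference of 1.48. With 3 control libraries no split leaves at least 2 on each side, and a split of technical replicates could not show such a peculiarity. Part of the excess of shared calls over independent lists may therefore come from the shared controls. Some chromosomes shifted alike in resistant and Sox10_KO cells, with medians of 0.44 and 0.26 for chromosome 1 and -0.4 and -0.38 for chromosome 7. Chromosomes 3 (0.01 and -0.3) and 17 (-0.24 and 0.02) did not. Such shifts enter r and the share of the same sign, and their part was not tested.

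**Figure D4:**
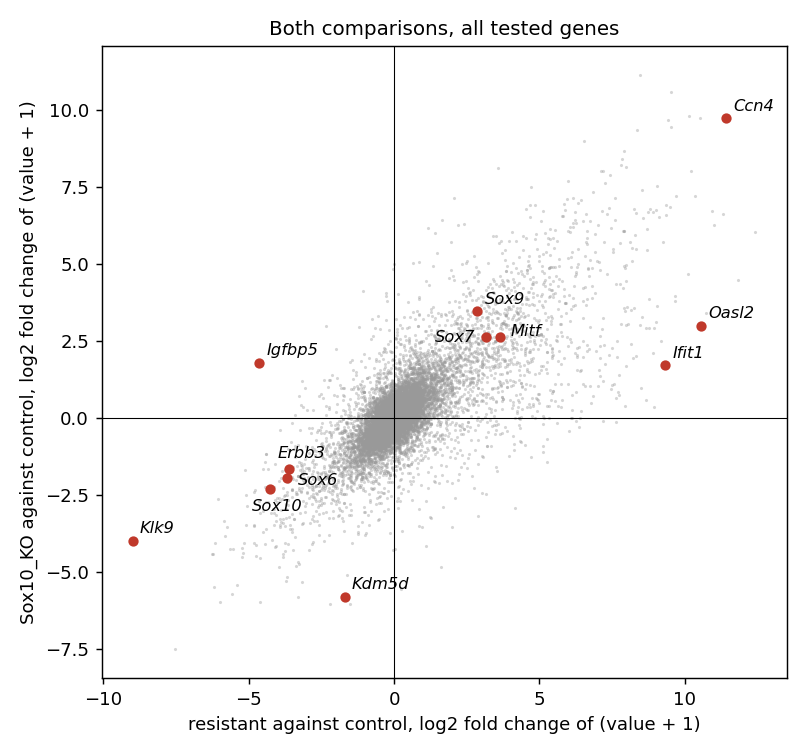
Log2 fold change of (value + 1) of every tested gene in resistant against control cells (x axis) and in Sox10_KO against control cells (y axis), with named genes in red. Most named genes lie in the quadrants of shared direction; Igfbp5 lies lower in resistant and higher in Sox10_KO cells, at 106.2 and 9208 against 2640 in control.

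As for RNA quality and the genome, 13 mitochondrially encoded transcripts showed 3 higher and 2 lower in resistant cells (2 and 2 adjusted over the list alone; camera adjusted p = 0.71) and 5 higher and 0 lower in Sox10_KO cells (on both adjustments; camera adjusted p = 0.15). Of 24 ribosomal protein genes, 3 were higher and 11 lower in resistant cells (3 and 13 adjusted over the list alone; camera adjusted p = 0.2), or 5 and 13 without Sox10_KO replicate 2. In Sox10_KO cells 2 were higher and 12 lower, on both adjustments (camera adjusted p = 0.032; adjusted p = 0.87 with an estimated correlation), and that call ended without Sox10_KO replicate 2 (adjusted p = 0.15) or control replicate 3 (0.095) and with equal library totals (0.088). Between resistant and Sox10_KO cells the mitochondrial list gave 1 higher and 6 lower (on both adjustments; camera adjusted p = 0.082, or 0.039 without resistant replicate 3; adjusted p = 0.65 with an estimated correlation in all libraries) and the ribosomal list 4 higher and 1 lower (1 and 1 adjusted over the list alone; camera adjusted p = 0.25). Genes of chromosome 1 were shifted as a set in resistant cells, with a median log2 fold change of 0.44 over 621 genes, so single changes of about this size are not separable there from a shift of the chromosome. This limit also applies to chromosomes 15 (0.41), 7 (-0.4), 16 (-0.35) and 2 (-0.33) in resistant cells, and 7 (-0.38) and 15 (0.36) in Sox10_KO cells. It applies as well to a 20 Mb window of chromosome 10, with medians of 0.7 in resistant and 0.91 in Sox10_KO cells.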

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

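Quantile normalization and library weights were chosen after the data were seen; the other alternatives were planned. Every fold change is log2. The counts of called genes and of their overlap stayed within 1.5 times their value with a pseudocount of 0.1 or 5, no filter, equal library totals and the replicate block, as did the counts of called genes with only the groups compared, where the overlap was not run. The stricter filter tests fewer genes: it gave 2760 higher genes in resistant against control, and at least 2-fold changes of 727 higher and 557 lower there, 607 and 557 in Sox10_KO against control and 370 and 193 in resistant against Sox10_KO, with 449 shared higher, 341 shared lower and 10 opposite. The test against a 1.5-fold change asks for more and gave 1805 higher and 1056 lower, 1412 and 1061, and 838 and 381 in the same order, with 286 genes at least 2-fold lower in resistant than in Sox10_KO cells and 16 opposite. It also ended 26 calls of single genes. Among them were Mitf (adjusted p = 0.25) and Zfp423 (0.0702) between the derived lines, and Ngfr (0.157) and Slc7a11 (0.0777) in Sox10_KO against control. Quantile normalization gave 1602 genes at least 2-fold lower in resistant than control and 845 than Sox10_KO cells, with 54 opposite; it moved the median of all genes from 0.024 to -0.118 in resistant against control, and equal totals moved it to 0.116, and to 0.109 in Sox10_KO against control, so changes are relative to such shifts. Library weights, which gave Sox10_KO replicate 2 a weight of 0.203, gave 55 opposite. Leaving out single libraries gave 27 to 55 opposite, the highest without Sox10_KO replicate 2. Beyond the filter and the 1.5-fold test, the cause was not tested.

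Leaving out single libraries gave ranges of 3684 to 4671 higher and 3472 to 4414 lower in resistant against control, 3600 to 4187 and 3531 to 4148 in Sox10_KO against control, and 2726 to 3731 and 2512 to 3431 in resistant against Sox10_KO. The genes whose direction turned were not called in those comparisons with all libraries at equal weight. In resistant against control, Sox5 went to -0.2 with quantile normalization and -0.03 with weights (leaving out libraries, -0.12 to 0.2), and Cdkn2a to 0.09 with equal totals and 0.04 with weights (-0.08 to 0.09). In Sox10_KO against control, Sox5 went to 0.05 with equal totals (-0.18 to 0.14), Egfr to -0.67 with quantile normalization and -0.59 with weights (-1.09 to 1.51), and Braf ranged from -0.03 to 0.55. In resistant against Sox10_KO, Sox5 went to -0.06 with quantile normalization (-0.05 to 0.14), Braf to 0.18 with weights (-0.29 to 0.29), and Sox4 ranged from -0.12 to 0.71, where it was called without Sox10_KO replicate 2 (adjusted p = 1.1e-06), as it was with weights (0.61; 0.00635). The called Egfr difference between resistant and control cells was also lost with a pseudocount of 0.1, no filter and quantile normalization. The Nrxn2 and Rnf165 calls between the derived lines were each lost in 10 settings besides the 1.5-fold test (adjusted p = 0.057 to 0.132 and 0.0522 to 0.107). Leaving out single control libraries gave Cdh5 changes of 7.29 to 8.49 in resistant against control and 5.2 to 6.39 in Sox10_KO against control, where Aldh3a1 ranged from 8.95 to 10.31. The Egfr call was lost without control replicate 2 (adjusted p = 0.168), control replicate 3 (0.115), resistant replicates 1 to 3 (0.0921, 0.108 and 0.0943) and Sox10_KO replicate 1 (0.052).

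List directions turned only where no camera call stood, and list values are medians. In resistant against control these were the SOX family with fry (-0.45), muscle and erythroid markers with equal totals (0.38; leaving out libraries, 0.02 to 0.56), mitochondrial genes (0.01 to 0.16) and immediate early genes (-0.1 to 0.06). In Sox10_KO against control they were mesenchymal genes (fry -0.09; -0.11 to -0.04), hypoxia and glycolysis (fry 0.12; 0.06 to 0.13), the WNT response with equal totals (-0.28), the SOX family (-0.76 to 0.29), cartilage targets (-0.83 to 0.98) and muscle and erythroid markers (-0.59 to 1.34). In resistant against Sox10_KO they were receptor tyrosine kinases (fry 0.09; 0.03 to 0.13), keratinocyte markers (0 to 0.36) and muscle and erythroid markers (-1.04 to 0.88). A median can keep its sign while the direction of the test turns. An estimated correlation ended 25 of the list calls, and fry, which does not compare a list with other genes, called 38 lists in camera's direction that camera did not, and 2 against it, mesenchymal genes (adjusted p = 0.0012) and hypoxia and glycolysis (0.013) in Sox10_KO against control.

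The replicate block left 4076 higher and 3826 lower genes in resistant against control, and among the genes named in the text ended 2 calls, Egfr there (adjusted p = 0.0647) and Sox7 in resistant against Sox10_KO (0.053). The numbers did not pair the libraries: 1 of 9 same-numbered pairs had deviations correlated above 0.1, and 5 of 18 best matches carried the library's own number. Planned but not run, for lack of whole counts, were the DESeq2 and voom tests and the rounding check; size factors were already in the values. For genes at values of 10 to 100, 50% to 60% of simulated 4-fold changes were found, and the part of depth in this was not tested.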

Other observations

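The tests of mixing between libraries, of another species, of a gain of chromosome 1, and of fibroblast and leukocyte RNA were chosen only after the results they address were seen. The neuron and other cell type lists were written after other neural transcripts had been seen in Sox10_KO replicate 2, but before the lists were tested; the remaining tests were written before their results. WNT response genes rose in 6 of 10 and fell in 3 in resistant cells, and rose in 4 and fell in 4 in Sox10_KO cells, on both adjustments (camera adjusted p = 0.38 and 0.93). The WNT inhibitor gene Apcdd1 rose from 383.4 ± 37.9 in control to 40830 ± 1900 in resistant (106-fold) and 13530 ± 2400 in Sox10_KO cells (34.9-fold). Axin2, a feedback gene of the same pathway, rose from 32 ± 6.28 to 1130 ± 57.1 (34.7-fold) and 211.7 ± 51.9, and Notum from 2.09 ± 2.56 to 765.2 ± 53.7 and 109.1 ± 28.2. Between the derived lines 5 WNT genes were higher and 2 lower in resistant cells (camera adjusted p = 0.12), or 5 and 1 without Sox10_KO replicate 2. TGF-beta response genes rose in 10 of 16 and fell in 3 in resistant cells and rose in 9 and fell in 2 in Sox10_KO cells (9 and 3 adjusted over the list alone; camera adjusted p = 0.14 and 0.15), and 5 were higher and 4 lower between the lines (0.79). Tgfb3, a ligand, rose 11.8-fold in resistant and 3.15-fold in Sox10_KO cells, while Pmepa1 fell from 2191 ± 228 to 502.9 ± 78.2 in resistant cells. Immediate early genes split into 6 higher and 7 lower of 16 in resistant cells (camera adjusted p = 0.91) and 4 higher and 10 lower in Sox10_KO cells (5 and 10 adjusted over the list alone; 0.11, or 0.049 without Sox10_KO replicate 3; adjusted p = 0.77 with an estimated correlation in all libraries). They were higher in 7 and lower in 1 in resistant against Sox10_KO cells (camera adjusted p = 0.012; adjusted p = 0.49 with an estimated correlation), a call that ended without Sox10_KO replicate 2 (adjusted p = 0.06). The orphan receptor gene Nr4a1 fell 12.1-fold in both lines, and Egr2 fell 7.07-fold in resistant and 17.2-fold in Sox10_KO cells.

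Hypoxia and glycolysis genes rose in 4 of 17 and fell in 11 in resistant cells, on both adjustments, with a median log2 fold change of -0.43 against a mean of 0.14 and a camera direction of down (camera adjusted p = 0.059). The list was called with equal library totals (0.041) and without Sox10_KO replicate 1 (0.047) or 2 (0.043). With an estimated correlation the adjusted p was 0.48 in all libraries and 0.19 without Sox10_KO replicate 2. In Sox10_KO cells 7 were higher and 8 lower (8 and 8 adjusted over the list alone; 0.93; median 0.12, mean 0.24, camera's direction down), and between the lines 4 were higher and 10 lower (0.12). The mean was pulled up by Egln3, an oxygen-sensing hydroxylase, at 2.17 ± 0.404 in control, 1408 ± 85.9 in resistant and 348.3 ± 34.3 in Sox10_KO cells, while the glycolytic regulator Pfkfb3 fell from 1285 ± 82.9 to 308.6 ± 56.6 and 293.8 ± 101. Of 22 oxidative phosphorylation genes, 7 rose and 9 fell in resistant cells and 9 rose and 4 fell in Sox10_KO cells (10 and 4 adjusted over the list alone; camera adjusted p = 0.55 and 0.59). In resistant against Sox10_KO cells 3 were higher and 12 lower (0.064, or 0.019 without Sox10_KO replicate 2, where the adjusted p was 0.67 with an estimated correlation). Drug efflux transporters rose in 4 of 6 and fell in 1 in resistant cells and split into 2 and 2 in Sox10_KO cells (camera adjusted p = 0.35 and 0.84), with 3 higher and 1 lower between the lines (0.22); without Sox10_KO replicate 2 the first counts were 4 and 2. The P-glycoprotein gene Abcb1b rose 2.25-fold in resistant and 3.21-fold in Sox10_KO cells, and Abcg2 fell 2.22-fold and 2.32-fold. SOX9 cartilage targets gave 1 higher and 3 lower of 8, 2 and 2, and 0 and 1 in the 3 comparisons (camera adjusted p = 0.6, 0.91 and 0.32), the first being 2 and 3 without Sox10_KO replicate 2. Among markers of other cell types, endothelial genes gave 2 higher and 0 lower of 3 in both comparisons with control (0.2 and 0.27) and 2 and 1 between the lines (0.63). The cadherin gene Cdh5 stood at 16 ± 15.6 in control, 2820 ± 68.3 in resistant and 659.6 ± 40.7 in Sox10_KO cells. Macrophage and leukocyte markers gave 0 and 0 of 2, 0 and 1, and 1 and 0 (0.8, 0.77 and 0.32). Keratinocyte markers gave 2 and 0 of 3, 2 and 0, and 1 and 1 (0.38, 0.24 and 0.95). Muscle and erythroid markers gave 0 and 0 of 2 in each (0.91, 0.91 and 0.9), or 0 and 1 in Sox10_KO against control and 1 and 0 between the lines without Sox10_KO replicate 2. Unless given, counts adjusted over the list alone were identical. Median, mean and camera direction also differed in sign in Sox10_KO against control for the SOX family, mesenchymal, WNT, cartilage and macrophage lists, and in resistant against Sox10_KO for the TGF-beta and keratinocyte lists.

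The transcripts that Sox10_KO replicate 2 alone held may come from RNA of other cells mixed into that library; mixing with another library of the study is argued against by the 67 genes at 1000 or more that stood at 50 or less in the 8 other libraries, since no library here could supply them. RNA from neural cells was in line with the neuron list, whose median log2 ratio over replicates 1 and 3 was 6.74, against 4.29 for neural progenitor, 1.64 for cardiomyocyte, 1.21 for astrocyte, 0.68 for epithelium, -0.09 for oligodendrocyte, -0.51 for lymphocyte, -0.77 for pluripotent stem cell and -1.4 for hepatocyte genes. In the neuron list 17 of 22 genes were over 2-fold and 10 were also expressed in the other libraries, among them its most abundant, Nefl and Tubb3, at 19580.4 and 14322.4 here and as high elsewhere. RNA of another species, whose reads would also match processed copies of conserved genes, was in line with a share of 32.3% annotated pseudogenes (21 of 65; 95% exact interval 21.2% to 45.1%) among genes found in this library alone, against 0.707% of 5942 genes at that level in replicates 1 and 3. The 65 genes were chosen as low in the other libraries and the 5942 as high in replicates 1 and 3. No share was computed for other genes low there, so the contrast cannot decide on another species. Neither the source nor the species was identified, both explanations can hold together, and a biological difference within the Sox10_KO group was not tested.

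Genes of chromosome 1 were shifted upward in resistant cells, with a median log2 fold change of 0.44 (95% interval 0.42 to 0.5, 621 genes). This interval, and the interval after GC removal below, came from resampling the genes. Genes are not independent, and neither interval holds the spread between libraries or clones. Chance assignment of genes to 20 chromosomes is argued against by a permutation p of 1e-04, the smallest that 10000 permutations can give, with a largest permuted median of 0.17. GC content as the whole cause is argued against by a median of 0.26 (0.21 to 0.29) after removal of its trend. The typical absolute median of a chromosome went from 0.12 to 0.21. The trend was fitted by least squares, so its removal can shift the medians of all chromosomes alike. How much of the fall from 0.44 went with GC content therefore cannot be told. A gain of the whole chromosome stays open: 100% of 10 windows of 20 Mb had a median above 0 (0.32 to 0.7), but with 84.4% of the genes above 0 this could hardly have come out otherwise, no DNA was measured, and a difference of this clone from the parental cells was not tested. All windows also lay above 0 on chromosome 1 in Sox10_KO cells (0.11 to 0.39) and below 0 on chromosomes 2 (-0.5 to -0.22) and 7 (-0.56 to -0.18) in resistant cells, and other chromosome medians included 15 (0.41), 7 (-0.4), 16 (-0.35) and 2 (-0.33) in resistant and 7 (-0.38), 15 (0.36), 3 (-0.3), 1 (0.26) and 2 (-0.25) in Sox10_KO cells, and chromosome 3 (0.3) between the lines, and their causes were not tested.

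Fibroblast genes were high in resistant libraries, to which RNA of fibroblasts or leukocytes grown along with the tumour line could contribute. Fibroblast RNA as the whole cause of the Col1a1 rise is argued against by the ratio of Col1a1 to Col1a2. Their chains assemble into a single collagen, and fibroblasts are taken to make both in similar amounts, with no fibroblast library measured here. The ratio was at least 97 in resistant, 5.12 to 15.3 in control and 1.67 to 2.06 in Sox10_KO libraries. It does not address the other markers, and Col1a2 also rose, to between 664.6 and 749.7 in resistant libraries. In Sox10_KO libraries, where 7 of 9 markers rose, the ratio does not argue against fibroblast RNA. Leukocyte RNA is argued against by a summed marker level 1.31 times that of control. A smaller share of fibroblast RNA beside a change in the resistant cells themselves stays open, and that change was not tested further.

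For the counts of called genes, 10 splits of 6 libraries are too few for a share under 0.05. The real split was the 1 with the most calls in each comparison. It gave 8083 genes in resistant against control and the highest other split 0, 7915 and 1 in Sox10_KO against control, and 6420 and 0 in resistant against Sox10_KO.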
